A study of Mus musculus with 10 samples.

How the data were processed

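The series holds RNA-seq of 10 mouse livers, 5 with a control AAV and 5 with an AAV encoding miR-181d-5p. Per the labels' protocols, total RNA was extracted with the mirVana kit and libraries were made with the TruSeq Stranded mRNA kit. The authors deposited 1 table of FPKM (fragments scaled by gene length and by the total of assigned reads) with 17274 genes by symbol and 1 column per sample. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.1, HTSeq 0.13.5, R 3.4.1 and DESeq2 1.18.1, with the mm10 build; the notes used here give no role or order. Whether reads were counted by strand is not given in the sources used here, so a gene and an overlapping antisense partner may share reads. The formula behind the FPKM is also not given in the sources used here and was worked out from the values.

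Columns were matched to samples by group and number in their names. Each FPKM value turned out to be a whole number of reads divided by a gene length and a library total. A search over whole gene lengths gave whole reads, within 0.02 of a read in each liver, for 17273 of 17274 genes (99.994%) and for all 12053 genes tested. The smallest length that fitted was kept, so a gene with reads in few livers can fit by chance. Of the recovered lengths, 206 equalled the merged exon length in the annotation. The same search on simulated reads recovered 100% of 427 genes with reads in all samples exactly. The recovered library totals ran from 18985912 to 20657019 reads, and at least 99.998% of each total lay in listed genes. In 57 genes, counted among the 17273, all livers were at 0. FPKM sums ran from 440782 to 502752. The lowest total over 10 livers of a tested gene was 38 reads. The unit remains FPKM, so no count test was the main test.

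For the main test, log2(FPKM + 1) values of genes with a mean FPKM of at least 0.5 over all 10 livers were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with group as the only term. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes such as Nr4a3. On simulated values with the real means and spreads, 97% of genes changed by 1 on the log2 scale and 78% of genes changed by 0.58 were called among 12053 genes. In that simulation 17 unchanged genes were called beside 200 changed ones, and 0 when nothing was changed. Genes were drawn independently, with the same SD in both groups, and only genes with a mean of at least 1 FPKM were changed. In the real livers genes vary together and spread differs between groups, so these shares do not give the power of the real test.

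Before the data were examined, 34 gene lists were written down for steatohepatitis liver, its cell types and miR-181. Camera tested the 33 with at least 5 measured members, with a preset correlation of 0.01. The list of pancreas, muscle and fat markers had 4 measured members and was not tested (median log2 change 0.11, 3 of 4 higher). An estimated correlation, fry and an exact permutation of livers over all labellings were the alternatives. Longest 3' UTRs were taken from GENCODE vM21, which is on the same build, from the base after the stop codon. Of the tested genes 97.6% had one, and the rest were not searched. Gene positions come from the same annotation, 1-based, and 16703 of the table's symbols were found in the reference gene names.

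The genes named in the text follow a rule fixed at the same time. It took the 10 genes per direction with the largest log2 change among those past the threshold with a mean of at least 1 FPKM in the higher group. Where fewer passed, it filled up to 5 by the smallest p, said not to pass, and it left out predicted genes, RIKEN clones and pseudogenes. It added Nr4a3, any miR-181 gene (0 found by symbol), up to 4 members with the smallest p of each list described, and the 5 genes with an 8mer and the smallest p.

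Alternatives were other pseudocounts, filters and scalings, robust fitting, array weights, a replicate block, leaving out each liver, fold thresholds, other list tests and other site definitions. Chosen after seeing the data were limma voom on the recovered reads, voom with quality weights, removal of a gene length trend from each liver (lowess with a span of 0.3) and the orderings of the letters of the 7mer-m8 site. No 2 livers of a group differed by as little as counting noise: the lowest chi-square per degree of freedom of a pair was 9.51. Spearman correlations within groups ran from 0.971 to 0.994. The labels give no batch. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.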

Results

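Gene expression was measured in 10 liver samples from wild-type mice with diet-induced nonalcoholic steatohepatitis, a fatty liver disease with inflammation and scarring. The diet lacked choline, was rich in fat and supplied its protein as defined amino acids, which loads the liver with lipid. The mice received adeno-associated virus (AAV), a gene delivery vector, into a vein. In 5 samples the vector was a control, and in the other 5 it encoded miR-181d-5p, a microRNA of the miR-181 family. Libraries of polyadenylated RNA gave 18985912 to 20657019 gene-assigned reads per sample, with 19118235 to 20337358 in the control group. A tested gene had a median of 503 reads per sample. The table holds 0 miR-181 genes, so the level of the microRNA in each liver is not known from these data. The labels number the samples without tying each to its own animal, so p-values measure the spread between these samples.

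The first comparison asked which genes differ between livers given the microRNA vector and livers given the control vector, and in particular Nr4a3. In what is known of the study, Nr4a3, which encodes an orphan nuclear receptor induced within minutes of many stimuli, was examined as a target of miR-181d-5p. Nr4a3 (chromosome 4, 48045153 to 48086447, mm10) stood at 1.26 ± 1.06 FPKM in control livers and 0.415 ± 0.126 FPKM in miR-181d-5p livers (SD, n = 5 each). That is 33.0% of the control mean, and rests on 796 reads in the control group against 264. Each miR-181d-5p liver lay below each control liver, from 0.251 to 0.561 FPKM against 0.589 to 3.14 FPKM. The two-sided exact permutation p was 0.007937, the smallest that relabelling 10 livers can give. Across all genes tested, limma gave a log2 change of -0.58 (SE 0.21) with an adjusted p of 0.269, so Nr4a3 did not pass. Control liver 5 held the 3.14 FPKM; without it the log2 change was -0.34 and the adjusted p 0.152, in a range of 0.140 to 0.535 over the 22 alternatives that test Nr4a3. A filter at a mean of 1 FPKM leaves it out. The log2 change was -1.18 with a pseudocount of 0.1, -1.29 by voom on recovered reads and -1.04 by voom with quality weights.

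**Figure D1:**
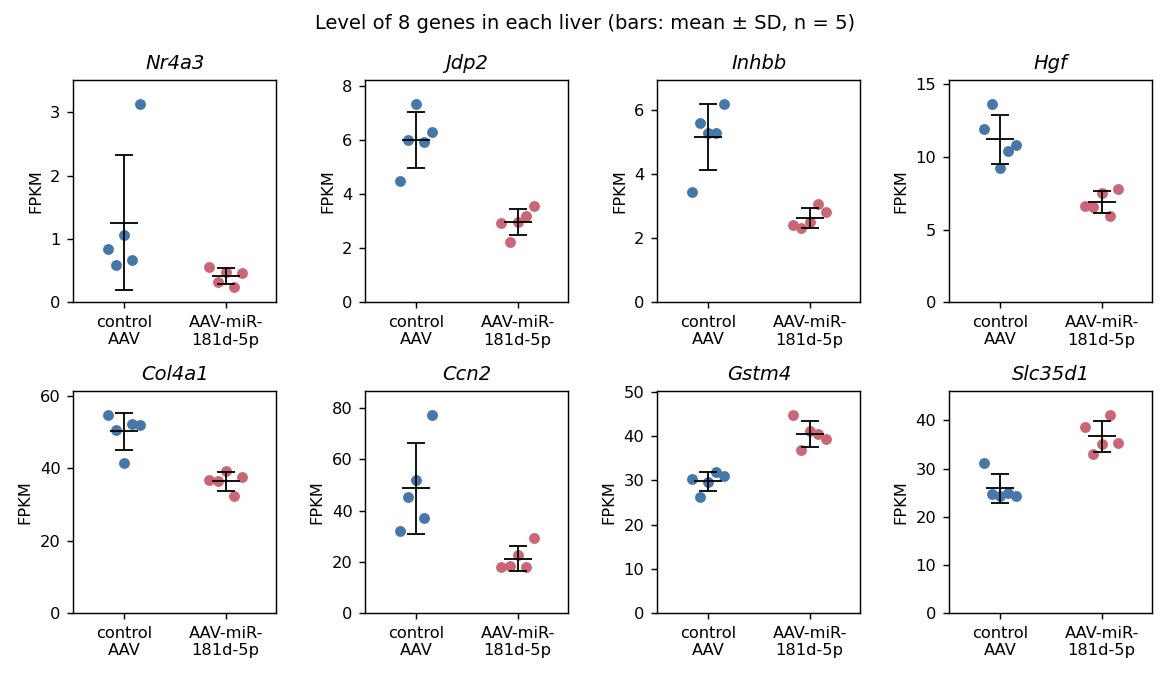
FPKM (vertical axis, from 0) of 8 genes in each of 5 control AAV livers (blue points) and 5 AAV-miR-181d-5p livers (red points), with bars for the mean and SD. All 8 genes separate the groups, and the control spread of Nr4a3 comes from 1 liver at 3.14 FPKM.

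The 5 genes with the smallest p in each direction follow, and none passed. Among those lower in miR-181d-5p livers, Jdp2, a repressor of AP-1 transcription factors, stood at 2.99 ± 0.484 FPKM against 6.02 ± 1.03 in controls, a log2 change of -0.81 (SE 0.12). Inhbb, which encodes the beta B subunit of activins and inhibins, stood at 2.62 ± 0.317 against 5.15 ± 1.03 FPKM. Hgf, which encodes hepatocyte growth factor and is made by stellate and endothelial cells in liver, stood at 6.88 ± 0.763 against 11.2 ± 1.68 FPKM. Cttnbp2nl was at 65.0% of its control mean and Col4a1, a chain of basement membrane collagen, at 72.6%. The genes with the smallest p in the other direction were Gstm4, a glutathione transferase, at 40.5 ± 2.87 against 29.8 ± 2.14 FPKM, a value that reads shared with near-identical family members make uncertain, and Slc35d1, a nucleotide-sugar transporter, at 36.7 ± 3.22 against 25.9 ± 2.95 FPKM. Dus1l, Hdhd3 and Tmem150a were at 128.3%, 145.6% and 129.3% of their control means. Of these 10 genes, 9 had groups that did not overlap, and Hdhd3 was the exception.

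None of the 10 passed the adjusted test. By limma, 0 of 12053 genes had an adjusted p under 0.05, the lowest being 0.142 for Jdp2. At an unadjusted p under 0.05 there were 1768 genes, 607 higher and 1161 lower. Without miR-181d-5p liver 4 there were 1071. That split depended on scaling: it was 345 higher and 1260 lower with FPKM rescaled to a common sum, and 997 and 942 after quantile normalization. In 298 genes (123 higher, 175 lower) the groups did not overlap, against 95.7 expected by chance, where 0.794% of genes would separate. Where genes vary together, the count can lie far from that expectation. Of 100 splits of the livers, 6, the real one included, gave as many, the highest other being 527. On whole reads recovered from the FPKM, limma voom called 0 genes, and voom with sample quality weights called 8 at an adjusted p of 0.0449. Their unadjusted counts were 1946 and 2274. Those 8 were Jdp2, Inhbb, Hgf, Cttnbp2nl, Gstm4 and Slc35d1 from above, with P4ha1 and AA986860, both lower and named after their values were seen. Without control liver 1, limma called Inhbb, Jdp2 and Slc35d1 (adjusted p = 0.00555, 0.0127 and 0.0255). Without control liver 5 it called AA986860 (adjusted p = 0.0467), and without miR-181d-5p liver 3 Npy (adjusted p = 0.0369). Over all alternatives the adjusted p of Jdp2 ran from 0.0127 to 0.355 and that of Inhbb from 0.00555 to 0.355. For Slc35d1 it ran from 0.0255 to 0.501, and for Gstm4, Hgf and Cttnbp2nl from 0.0449 to 0.501. Spread was unequal: the median SD of log2 values was 0.170 in controls and 0.106 in miR-181d-5p livers, and 76.1% of genes varied more in controls.

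The genes above lie at the following positions on mm10. Jdp2 spans 85599027 to 85639878 and Lpin1, described further on, 16535669 to 16610966 on chromosome 12. Inhbb spans 119415465 to 119422248 on chromosome 1, and Hgf 16553495 to 16620152 on chromosome 5. Col4a1 spans 11198423 to 11312826 on chromosome 8. Cttnbp2nl (105001915 to 105053146) and Gstm4 (108040408 to 108044894) are on chromosome 3. Slc35d1 (103170649 to 103215164) and Hdhd3 (62499008 to 62503467) are on chromosome 4. Dus1l spans 120789201 to 120796403 on chromosome 11, and Tmem150a 72355447 to 72359762 on chromosome 6.

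The second comparison asked how groups of genes fixed for this tissue and treatment moved. Genes of stellate cell activation and extracellular matrix, the scar-forming programme of the liver, were lower almost without exception. Of 55 measured members 54 were lower, with a median log2 change of -0.39. Ccn2, a matricellular protein induced by TGF-beta, stood at 21.3 ± 4.80 against 48.8 ± 17.7 FPKM, a log2 change of -1.12 (SE 0.21). Col14a1, a fibril-associated collagen, stood at 22.0 ± 2.0 against 29.7 ± 3.09 FPKM, and Bgn, a small proteoglycan, at 129 ± 13.3 against 178 ± 28.8 FPKM. Col4a1 had the smallest p of the list. Fibrillar collagen and myofibroblast genes, named after their values were seen, had log2 changes of -0.50 (Col1a1), -0.42 (Col3a1) and -0.49 (Acta2). No member passed over all genes, and 31, all lower, passed when adjusted over the list alone. The camera test with a preset correlation of 0.01 gave an adjusted p of 1.76e-17. With an estimated correlation the adjusted p was 0.31, so the call was lost. The mean of the list per liver had an exact permutation p of 0.0159, or 0.175 adjusted over 33 lists. The groups overlapped in this mean, with control liver 3 at -0.22 relative to the control mean and miR-181d-5p livers at -0.71 to -0.19.

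Markers of stellate cells and fibroblasts were lower in 18 of 21 members, with a median log2 change of -0.14. Cygb and Bmp5, named after their values were seen, passed when adjusted over the list alone, with log2 changes of -0.38 and -0.36. By camera the adjusted p was 0.00196, and 0.31 with an estimated correlation. Without control liver 5 it was 0.0916, in a range of 3.36e-04 to 0.31 over all alternatives. The list mean separated the groups narrowly, with controls down to -0.083 and miR-181d-5p livers up to -0.093. Its exact permutation p was 0.007937, or 0.131 adjusted over 33 lists. Liver endothelial markers had a median of -0.09, with 22 of 32 members lower. Their camera adjusted p of 0.0144 became 0.478 with an estimated correlation, and 0.364 without control liver 5, 0.0840 without miR-181d-5p liver 3 and 0.0984 with array weights, in a range of 0.0021 to 0.478. The mean change of -0.10 was -0.06 with a gene length trend removed from each liver. Kupffer cell markers, which mark the resident macrophages of the liver, split into 9 higher and 10 lower and were not called (adjusted p = 0.835).

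**Figure D2:**
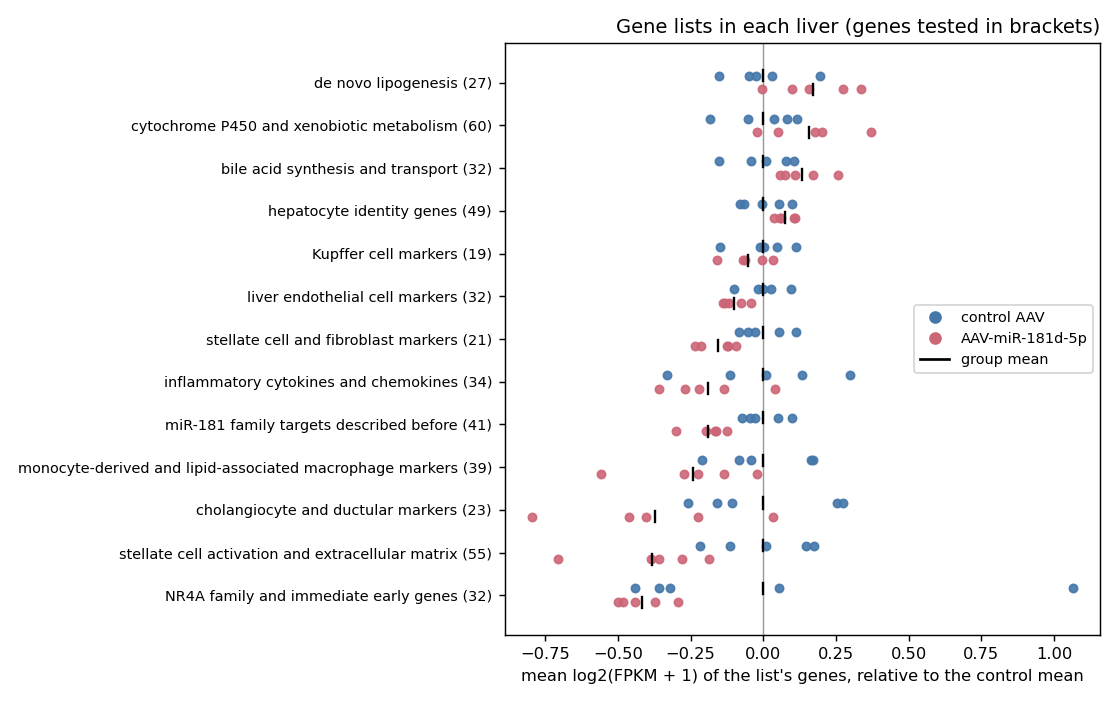
Mean log2(FPKM + 1) of the genes of 13 lists in each liver, relative to the control mean (horizontal axis). Blue points are 5 control AAV livers, red points 5 AAV-miR-181d-5p livers and black ticks the group means, and numbers in brackets are genes tested. The matrix list averages -0.38 in miR-181d-5p livers, and 1 control liver stands at 1.07 for immediate early genes.

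Immediate early genes, which include the NR4A family and are transcribed within minutes of a stimulus, were lower in 31 of 32 members, with a median log2 change of -0.37. Per1, a clock gene that is also induced by glucocorticoids, stood at 3.52 ± 1.13 against 6.77 ± 1.20 FPKM. The Kruppel-like factors Klf6 (26.6 ± 2.42 against 34.9 ± 4.41 FPKM), Klf10 (5.92 ± 1.23 against 8.59 ± 1.26) and Klf4 (0.776 ± 0.0863 against 1.29 ± 0.346) followed by p. The log2 change of Klf4, -0.36, was -0.64 with a pseudocount of 0.1 and -0.67 by voom. No member passed over all genes, and 7 passed, all lower, when adjusted over the list alone. Nr4a3 is on this list and was not among the 7 (adjusted p = 0.0695). The camera adjusted p was 1.05e-06, and 0.478 with an estimated correlation. Control liver 5 stood 1.07 above the control mean on this list. Without it the mean change shrank from -0.42 to -0.15 and the call was lost (adjusted p = 0.0513, in a range of 1.78e-11 to 0.478 over all alternatives).

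Genes described before as miR-181 family targets were lower in 39 of 41 members, with a median log2 change of -0.12 and a mean of -0.19. Timp3, an inhibitor of matrix metalloproteinases, stood at 11.7 ± 1.82 against 17.9 ± 3.20 FPKM, and Bcl2, which blocks apoptosis, at 0.858 ± 0.0905 against 1.28 ± 0.158 FPKM. The log2 change of Bcl2, -0.29, was -0.52 with a pseudocount of 0.1 and -0.55 by voom. Klf6 is on this list too, as is Nr4a3. Egr1, Fos, Dusp5 and Dusp6, named after their values were seen, are also shared with the immediate early list. Their log2 changes were -0.75, -0.64, -0.55 and -0.12. Fos and Egr1 stood at 142 and 96.2 FPKM in control liver 5, against at most 15.2 and 25.2 in the other 9 livers. Part of the lower mean may thus belong to the immediate early genes. Gata6, a transcription factor, stood at 4.30 ± 0.612 against 5.77 ± 0.652 FPKM. When adjusted over the list alone 6 members passed, all lower, and over all genes none. The camera adjusted p of 3.42e-05 became 0.31 with an estimated correlation. The list mean separated the groups fully, with an exact permutation p of 0.007937, or 0.131 adjusted over 33 lists.

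The last comparison asked whether genes carrying a miR-181 seed match were lower as a class, since microRNAs pair with 3' UTRs through positions 2 to 8 of their sequence. For miR-181 these read ACAUUCA. Of 11764 tested genes with an annotated 3' UTR, 2700 held an 8mer (TGAATGTA), a 7mer-m8 (TGAATGT) or a 7mer-A1 (GAATGTA) match and 9064 held none. Genes with a match had a mean log2 change of -0.06 and 64.4% were lower, against -0.02 and 51.8% for those without. The difference of -0.042 had a two-sided exact permutation p of 0.31. The 697 genes with an 8mer differed by -0.050 (exact permutation p = 0.278). Median 3' UTR length was 2274 nt with a match and 862 nt without. With 3' UTR length, GC content and expression in the model the difference was -0.0081 (exact permutation p = 0.143). Within 5 classes of 3' UTR length it ran from -0.033 to 0.0017, and the lowest exact permutation p, 0.0159 for the longest UTRs, was 0.0794 after Benjamini-Hochberg adjustment over the 5 classes. The difference passed under 2 settings: without control liver 5 (-0.065, exact permutation p = 0.0397) and with a gene length trend removed from each liver (-0.016, exact permutation p = 0.0317), in a range of 0.0317 to 0.595 over all alternatives.

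**Figure D3:**
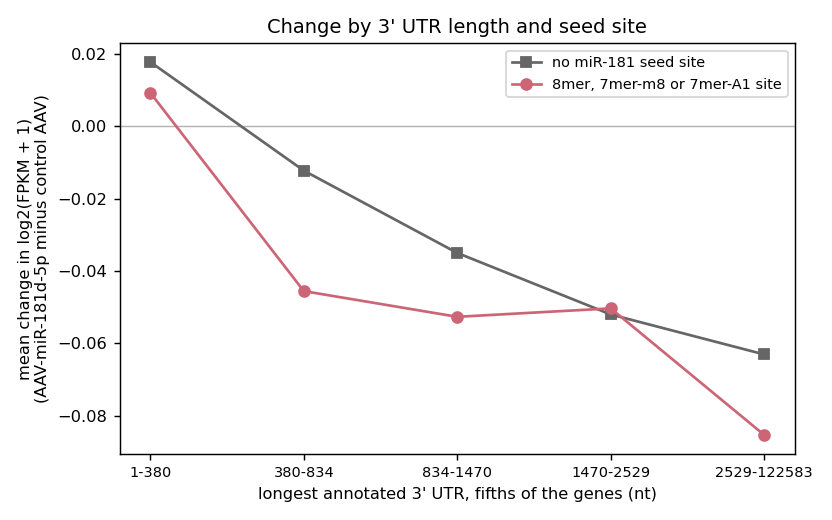
Mean change in log2(FPKM + 1) between AAV-miR-181d-5p and control AAV livers (vertical axis) for genes in 5 classes of longest annotated 3' UTR (horizontal axis, nt), with a miR-181 seed match (red circles) or without (grey squares); no error is drawn. The mean ran from 0.018 in the shortest class to -0.063 in the longest for genes without a match, and from 0.0092 to -0.085 for genes with 1.

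Nr4a3 holds 1 such match, a 7mer-m8 at 48085142 to 48085148 on chromosome 4, in the 3' UTR within exon 8 of 8. It begins at base 1790 of 3095 of the 3' UTR, in the context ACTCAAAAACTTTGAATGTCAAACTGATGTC. The 5 genes with an 8mer and the smallest p were Timp3, Picalm, Ahnak, Bcl2 and Klf6, all lower, none passing over all genes (adjusted p = 0.221 for each by limma). Picalm, a clathrin adaptor, stood at 49.3 ± 0.702 against 57.9 ± 1.44 FPKM, with a log2 change of -0.23 that was -0.09 with a gene length trend removed from each liver. Ahnak, a giant scaffold protein, stood at 3.10 ± 0.534 against 4.86 ± 0.908 FPKM. The 8mers of these 5 genes lie in the 3' UTR part of the last exon of the transcript searched. The Timp3 site is at 86349416 to 86349423 on chromosome 10 (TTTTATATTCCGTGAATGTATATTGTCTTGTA). The Picalm site is at 90211315 to 90211322 on chromosome 7 (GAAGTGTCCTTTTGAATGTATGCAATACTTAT), and the Ahnak site at 9019158 to 9019165 on chromosome 19 (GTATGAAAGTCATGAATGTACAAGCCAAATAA). For each gene the longest annotated 3' UTR was searched, and whether livers use it was not tested, the one of Ahnak, at 872 nt, included. The Bcl2 site is at 106539830 to 106539837 on the reverse strand of chromosome 1 (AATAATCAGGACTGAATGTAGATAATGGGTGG). The Klf6 site is at 5870348 to 5870355 on chromosome 13 (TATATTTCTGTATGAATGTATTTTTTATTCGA).

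Macrophage and bile duct markers were lower too. Of 39 markers of monocyte-derived and lipid-associated macrophages, which accumulate in steatohepatitis, 34 were lower, with a median log2 change of -0.25. Adgre1, which encodes F4/80, stood at 33.0 ± 3.19 against 42.9 ± 4.56 FPKM, and Mpeg1, a pore-forming macrophage protein, at 132 ± 14.6 against 180 ± 28.5 FPKM. The Fc receptor genes Fcgr1 and Fcgr3 were at 75.2% and 74.0% of control, and reads of such related genes may be split by the authors' counting. When adjusted over the list alone 5 members passed, all lower: Adgre1, Mpeg1, Fcgr1, Fcgr3 and Csf1r. Spp1, Gpnmb, Trem2, Ccr2 and Cx3cr1 were not among them, with log2 changes of -0.75, -0.31, -0.21, -0.13 and -0.10. They and Csf1r were named after their values were seen. Whether monocyte-derived or lipid-associated macrophages were lower beyond macrophages in general was not tested. The camera adjusted p was 3.03e-06, and 0.478 with an estimated correlation. The list mean overlapped between the groups, with control liver 1 at -0.21 relative to the control mean and miR-181d-5p livers at -0.56 to -0.02 (exact permutation p = 0.0714, or 0.262 adjusted over 33 lists). All 23 cholangiocyte and ductular markers were lower, with a median of -0.37. Sox9, a ductular transcription factor, stood at 2.09 ± 0.740 against 3.86 ± 0.839 FPKM and was the 1 member that passed when adjusted over the list alone. Ezr, Cd24a and Cldn4 had log2 changes of -0.37, -0.65 and -0.65. Here the camera adjusted p of 3.33e-06 became 0.478 with an estimated correlation. The groups overlapped in this list mean too: control livers 1 and 3 stood at -0.16 and -0.26, and miR-181d-5p livers 3 and 4 at 0.03 and -0.80 (exact permutation p = 0.0714, or 0.262 adjusted).

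Inflammatory cytokine and chemokine genes were lower in 30 of 34 members, with a median of -0.13. Vcam1, an adhesion molecule for leukocytes, stood at 30.8 ± 5.0 against 43.8 ± 5.76 FPKM and alone passed when adjusted over the list alone. Ccl6, Tnfrsf1b and Ltb were at 77.2%, 80.2% and 68.3% of control. The camera adjusted p of 8.72e-04 became 0.478 with an estimated correlation, and 0.283 without control liver 5, where the mean change shrank from -0.19 to -0.11, in a range of 1.28e-06 to 0.478 over all alternatives.

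Some lists of hepatocyte metabolism were higher, while fatty acid oxidation (adjusted p = 0.189), lipid droplet (0.337) and glycolysis (0.883) lists were not called by camera. Hepatocyte identity genes were higher in 38 of 49 members, with a mean log2 change of 0.07 (camera adjusted p = 8.10e-04, and 0.31 with an estimated correlation). After quantile normalization that mean was 0.04 and the call was lost (adjusted p = 0.264, in a range of 4.61e-05 to 0.31 over all alternatives), and with FPKM rescaled to a common sum the mean was 0.05. Beside these lists and those of lipogenesis and bile acids, markers of macrophages, cholangiocytes and stellate cells with fibroblasts were lower, with mean log2 changes of -0.24, -0.37 and -0.16. Cytochrome P450 and xenobiotic metabolism genes were higher in 51 of 60 members, with a median log2 change of 0.12. Gstm1, a glutathione transferase, stood at 2526 ± 219 against 1979 ± 152 FPKM, and Cyp2d10 at 259.8 ± 5.23 against 224 ± 19.8 FPKM. Cyp2c29 and Cyp3a25 were at 182.4% and 124.3% of control, and without miR-181d-5p liver 4 the log2 change of Cyp2c29 was 0.43 and not 0.72. These genes belong to families of close paralogs, so reads may be split between members. The camera adjusted p was 2.69e-07, and 0.31 with an estimated correlation, and the mean change of 0.16 was 0.10 without miR-181d-5p liver 4.

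De novo lipogenesis genes were higher in 22 of 27 members, with a median of 0.17. Srebf1, the transcription factor that drives the pathway, stood at 54.9 ± 16.8 against 32.5 ± 11.6 FPKM. Agpat2 and Me1, an acyltransferase of triglyceride synthesis and the malic enzyme that supplies NADPH, were at 125.4% and 124.7% of control. Lpin1, which acts both as a phosphatidate phosphatase and as a transcriptional coactivator, went against the list at 8.32 ± 3.10 against 16.3 ± 4.78 FPKM, and was the 1 member that passed when adjusted over the list alone. The camera adjusted p was 2.48e-05, and 0.31 with an estimated correlation.

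Bile acid synthesis and transport genes were higher in 27 of 32 members, with a median of 0.13. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 30.6 ± 10.6 against 17.3 ± 5.84 FPKM, and Hsd3b7, a later enzyme of the pathway, at 185 ± 22.2 against 148 ± 14.4 FPKM. Amacr and Abcb11, the bile salt export pump, were at 120.1% and 124.2% of control. No member passed over all genes, and none of the cytochrome P450 or bile acid members passed when adjusted over the list alone. For bile acid genes the camera adjusted p was 3.42e-05, and 0.31 with an estimated correlation. In all, 22 of 33 lists were called by camera with the preset correlation, 9 higher and 13 lower, and 0 with an estimated correlation, by fry or by permuting livers. The smallest exact p of 5 against 5 livers is 0.007937. Adjusted over 33 lists, a list at that floor can pass only if several others reach it too. The 0 by permuting livers therefore says little about any single list.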

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

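The tests of explanations below, those on splits of the livers included, were chosen after their results were seen. The exception is the test on orderings of the site, chosen after seeing the data but before its own result. In 160 groups of 5 livers (named genes and list means), 9 had a liver far from the others by the gap relative to the range, and chance gives about 1 in 20, or 8. Slc35d1 was highest in control liver 1 (31.2 FPKM against 24.3 to 25.02, ratio 0.88), and Inhbb lowest there (3.43 against 5.26 to 6.19, ratio 0.717). Col4a1 was lowest in control liver 3 (41.6 against 50.7 to 54.8 FPKM, ratio 0.718). Tnfrsf1b was lowest in miR-181d-5p liver 4 (17.2 against 23.0 to 25.7 FPKM, ratio 0.727), and Lpin1 highest in miR-181d-5p liver 5 (13.7 against 6.39 to 7.87 FPKM, ratio 0.736). Among list means, ribosomal proteins were highest (ratio 0.784) and cell cycle genes lowest (ratio 0.751) in miR-181d-5p liver 3, and acute phase genes highest in miR-181d-5p liver 1 (ratio 0.802).

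Nr4a3 was highest in control liver 5 (3.14 against 0.589 to 1.07 FPKM, ratio 0.722). That liver also stood apart for other genes induced by handling or stress, named after their values were seen: Fos was at 142 FPKM against 5.56 to 15.2 in the other 9 livers, Egr1 at 96.2 against 11.6 to 25.2, and Nr4a1 at 26.2 against 2.59 to 5.64. Without it the log2 change went from -0.58 to -0.34 (95% interval -0.55 to -0.13 by limma for this gene alone; adjusted p = 0.152 over all genes, in a range of 0.140 to 0.535 over the 22 alternatives that test it), which argues against this liver as the source of all of the change, though not of part of it. Whether Nr4a3 differs apart from the other immediate early genes stays open, as it turns on the pseudocount: without control liver 5, Nr4a3 minus their mean differed by -0.19 with a pseudocount of 1, which understates changes of low genes (exact permutation p = 0.111), by -0.33 with 0.5 (exact permutation p = 0.0556) and by -0.60 with 0.1 (exact permutation p = 0.0317). Their own mean differed by -0.14 with a pseudocount of 1 (exact permutation p = 0.222). Direct repression through the 7mer-m8 site stays open and untested.

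The lower matrix list was set against 3 technical explanations. A lower share of all non-hepatocyte cells alike is argued against only weakly. The change of the matrix list minus the mean change of the endothelial and Kupffer lists was -0.31 (exact permutation p = 0.0159). The matrix list also lay below the macrophage, stellate and B cell lists (exact permutation, adjusted p = 0.0317 for each over 10 lists). All of these gaps are hard to weigh, as higher members raise the endothelial, Kupffer, B cell and macrophage means. The matrix list was also compared after it was seen to have the smallest camera p of the 33 lists. Of 32 endothelial members 10 were higher and 22 lower, and of 19 Kupffer members 9 were higher and 10 lower. Of 10 B cell members 4 were higher, among them Xbp1 and Sdc1 (log2 changes 0.18 and 0.15), and 6 lower. Of 39 macrophage members 5 were higher, among them Apoe, Apoc4, F10 and Ctsl, and 34 lower. The matrix list shares Spp1 and Mmp12 with the macrophage list, Spp1 with the cholangiocyte list too, and Dcn and Pdgfrb with the stellate list. It did not separate from cholangiocyte (difference -0.013), dendritic cell (-0.12), T and NK cell (-0.23) or neutrophil markers (-0.25), with exact permutation adjusted p of 0.913, 0.432, 0.288 and 0.113, so a lower share of some cell types stays open. A gene length trend between livers is argued against, as the list mean was -0.34 with the trend removed and -0.38 as deposited, and so is control liver 5 alone, with -0.34 without it (exact permutation p = 0.0238). An effect of miR-181d-5p itself stays open and untested.

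For the shift of genes with a seed site, longer 3' UTRs are a candidate explanation: adjusting for length, GC content and expression left -0.0081 of -0.042. Any match of the same letters is another. The 7mer-m8 site ranked 20 of 210 orderings of its letters by adjusted shift, lowest first, outside the lowest 5%. A small effect through the site stays open, with the 2 settings under which the shift passed.

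Of 100 splits of the 10 livers, drawn from 126, 4, the real one included, gave as many genes at an unadjusted p under 0.05 as the real 1768, the highest other being 2342. That share is under 5% by a narrow margin, and without miR-181d-5p liver 4 the count was 1071, for which splits were not drawn. For the 298 genes whose groups did not overlap, 6 of 100 splits, the real one included, gave as many, the highest other being 527, so chance is not excluded. For genes past the adjusted threshold the real count was 0 and the highest other 5, so all 100 splits gave as many. For lists called by camera with the preset correlation, 9 of 100 splits gave as many as the real 22, the highest other being 25 and the median 16, so chance is not excluded and the preset test calls many lists for unrelated splits.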

How the results depend on the processing

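Settings with voom on recovered reads or a removed length trend were chosen after seeing the data. The count of genes past the adjusted threshold, 0 by the main test, was 1 with the replicate block (Ccn2, adjusted p = 0.0137, in a range of 0.0137 to 0.501) and 8 with voom and quality weights. Leaving out 1 liver gave 0 to 3: 3 without control liver 1 (Inhbb, Jdp2, Slc35d1), 1 without control liver 5 (AA986860) and 1 without miR-181d-5p liver 3 (Npy); the cause was not tested. Every other setting gave 0. The count at an unadjusted p under 0.05 ran from 1071, without miR-181d-5p liver 4, to 2587, without control liver 5. With the length trend removed it held 1114 higher and 1041 lower.

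The count of called lists, 22, ran from 18 to 23 over settings that kept the preset correlation and was 0 with an estimated correlation, 0 by fry and 0 by permuting livers. Those 3 tests allow for genes that vary together between livers. By permutation, a list can pass after adjustment only if several lists reach the smallest possible p of 0.007937. The seed-site shift of -0.042 was lower than 0 in all settings, from -0.065 to -0.0081. It passed with the length trend removed (-0.016) and without control liver 5; leaving out 1 liver gave -0.065 to -0.022; the cause was not tested. No named gene and no called list changed direction in its test, though the mean of NRF2 targets, 0.02, ran from -0.012 to 0.042. Over all named genes and settings, 1070 values stayed on their side of the threshold and 10 crossed it in the same direction. For lists the numbers were 674 on the same side, 17 newly called and 101 no longer called, most by the 3 other tests.

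The replicate numbers did not pair the livers: deviations of same-numbered livers correlated at -0.08, 0.015, -0.28, -0.18 and -0.28, and no liver correlated best with its own number. The block moved the count of called genes from 0 to 1 and kept 22 lists. With the block 32 labellings exist and no exact p under 0.0625 is possible for the seed-site shift. Nr4a3, at 31 to 390 reads per liver, is the named gene most limited by depth, and its change ran from -1.29 to -0.34 over 22 alternatives; a filter at a mean of 1 FPKM leaves it out.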

Other observations

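The genes named below and the tests on heat shock and YAP targets were chosen after their values were seen. Antigen presentation and interferon lists were each called lower in miR-181d-5p livers by camera with the preset correlation, with overlap between the groups. Dendritic cell and MHC class II markers were lower in 19 of 20 members, with a median log2 change of -0.19 (adjusted p = 1.41e-04, and 0.385 with an estimated correlation). Cd74, the invariant chain of MHC class II, stood at 492 ± 74.5 against 776 ± 289 FPKM and H2-Aa at 226 ± 34.8 against 353 ± 129.5 FPKM (SD, n = 5 each). The list mean of control liver 1 was -0.35 relative to the control mean, below 4 of the 5 miR-181d-5p livers. Interferon response genes were lower in 41 of 53 members, with a median of -0.25 (adjusted p = 4.45e-04, and 0.564 with an estimated correlation). Without control liver 3 the adjusted p was 0.0506, in a range of 8.19e-09 to 0.564 over all alternatives, and without control liver 2 the mean change was -0.14 and not -0.22. On this list control livers 1 and 5 stood at -0.39 and -0.30, against -0.34 to -0.03 in miR-181d-5p livers. T and NK cell markers had a median of -0.17 (adjusted p = 0.00919, and 0.564 with an estimated correlation). That call was lost without control liver 4, with a mean of -0.04 in place of -0.15, and without control liver 3 or miR-181d-5p liver 3. The mean was -0.09 after quantile normalization, -0.25 with a pseudocount of 0.1 and -0.26 by voom on recovered reads. Apoptosis and p53 targets had a median of -0.07 (adjusted p = 0.031, and 0.564 with an estimated correlation). That call was lost without control liver 5 (adjusted p = 0.314), without miR-181d-5p liver 2 (0.165) and with array weights (0.0684), in a range of 0.00597 to 0.564, and the mean of -0.09 was -0.06 after quantile normalization. Circadian clock genes had a median of -0.09 (adjusted p = 0.0338, and 0.478 with an estimated correlation). That call was lost without control liver 1, 3 or 5, without miR-181d-5p liver 1 or 3, with array weights, with no filter and with FPKM rescaled to a common sum. Neutrophil (median -0.12), B cell (-0.05) and cell cycle (-0.07) lists were not called. The neutrophil list was called without control liver 1, 2 or 4 or miR-181d-5p liver 1 and with the length trend removed, with a mean of -0.18 without control liver 1, and its mean of -0.13 was -0.04 without control liver 5, -0.08 after quantile normalization, -0.22 with a pseudocount of 0.1 and -0.24 by voom on recovered reads. The cell cycle list was called without control liver 4 (mean -0.08), and its mean of -0.06 ran from -0.09 with FPKM rescaled to a common sum to -0.0020 after quantile normalization over all alternatives.

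In the other direction, all 75 measured oxidative phosphorylation genes were higher, by a median log2 change of 0.09 (adjusted p = 2.69e-07, and 0.564 with an estimated correlation). Their mean change of 0.10 was 0.043 without control liver 1, 0.046 without control liver 2 and 0.17 without control liver 5. The list mean was -0.21, -0.20 and 0.28 in control livers 1, 2 and 5, whose levels followed gene length across genes with Spearman correlations of 0.598, 0.494 and -0.396; genes are not independent replicates. Ribosomal protein means there were -0.23, -0.17 and 0.30. The correlation with gene length was -0.26 and -0.020 in control livers 3 and 4, and ran from -0.21 to 0.056 in miR-181d-5p livers. With the length trend removed from each liver the oxidative phosphorylation list mean was 0.093. Cholesterol synthesis genes had a median of 0.08 (adjusted p = 0.00154, and 0.478 with an estimated correlation), and their mean of 0.10 was 0.05 without control liver 3. Genes of the unfolded protein response (median 0.08, adjusted p = 0.00725, 0.564 with an estimated correlation) lost their call after quantile normalization and without control liver 2 or miR-181d-5p liver 3, where the mean of 0.09 was 0.05. Leaving out 1 liver gave means from 0.045 to 0.14. Choline and one-carbon genes (median 0.04, adjusted p = 0.0163, 0.433 with an estimated correlation) lost their call after quantile normalization and without control liver 4 or miR-181d-5p liver 4, the mean of 0.045 being 0.020 without the latter, 0.016 with FPKM rescaled to a common sum and 0.079 with the length trend removed. NRF2 targets had a median of 0.09 and a mean of 0.02 (adjusted p = 0.0211, 0.478 with an estimated correlation). That mean turned below 0 with FPKM rescaled to a common sum, after quantile normalization and without control liver 1 or 2 or miR-181d-5p liver 1, and ran from -0.012 to 0.042. The call was lost after quantile normalization, with the length trend removed and without control liver 1, 2 or 4 or miR-181d-5p liver 1 or 5. Ribosomal protein (median 0.02), fatty acid oxidation (0.01), lipid droplet (0.03), glycolysis (-0.01), acute phase (-0.01), erythroid (-0.07) and sex-biased (-0.01) lists were not called. Without control liver 5 ribosomal protein genes were called higher, with a mean of 0.096 in place of 0.020 (adjusted p = 2.91e-10, in a range of 2.91e-10 to 0.925). They were also called without control liver 3 or miR-181d-5p liver 1 or 5, with no filter, with median-of-ratios scaling and with array weights. Fatty acid oxidation genes were called higher without control liver 3 (mean 0.074) and without miR-181d-5p liver 1 or 3, and erythroid genes without control liver 5 (mean 0.17). Under another scaling or with the length trend removed, the means of the ribosomal protein, fatty acid oxidation, lipid droplet, glycolysis, acute phase and B cell lists changed sign. The median and mean of fatty acid oxidation, lipid droplet and sex-biased lists differed in sign, and camera ranked glycolysis, acute phase and erythroid lists toward higher against a median below 0.

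The groups of heat shock genes and YAP targets were put together only after some members had been seen to be lower. Heat shock genes were lower in 17 of 22 members. Hspa1b, a stress-inducible chaperone whose reads may be shared with its near-identical neighbour Hspa1a, stood at 11.3 ± 8.20 against 42.9 ± 24.6 FPKM, and Dnajb1, its co-chaperone, at 13.6 ± 3.61 against 24.3 ± 5.85 FPKM (SD, n = 5, adjusted p = 0.221 over all genes by limma). Of 19 members not looked at before and on no fixed list, 14 were lower. Their mean log2 change was -0.20 (exact permutation p = 0.0397), and -0.23 without control liver 5 (exact permutation p = 0.0317). These 19 may vary together with the members seen before, so these p-values are no independent check. For the whole list the unadjusted camera p of 3.1e-06 became 0.115 with an estimated correlation. This is consistent with a lower heat shock response in miR-181d-5p livers, or with a difference in how tissue was handled, which was not tested.

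Target genes of YAP and TEAD, transcription regulators that respond to tissue stiffness, were lower in 21 of 23 members, with a mean log2 change of -0.32. The matrix list and the markers of cholangiocytes and of stellate cells and fibroblasts were also lower in miR-181d-5p livers, with mean log2 changes of -0.38, -0.37 and -0.16. In 17 members on no fixed list and not looked at before, 15 were lower, with a mean log2 change of -0.23 (exact permutation p = 0.007937, the smallest that relabelling 10 livers can give), and -0.24 without control liver 5. Of these, Axl and Myof had log2 changes of -0.26 and -0.57. For the whole list, which includes Ccn2 and other genes seen before, the unadjusted camera p of 6.48e-07 became 0.0191 with an estimated correlation. By the same test the bile acid list had an unadjusted p of 0.0189, which was 0.31 after adjustment over 33 lists. The 17 members may vary together with those seen before, so their exact permutation p is no independent check.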
